A study of Bos taurus with 20 samples.

How the data were processed

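RNA from bovine longissimus dorsi muscle of 2 crosses at 10 ages was hybridised to two-colour Agilent arrays, and per the submitters' processing notes the scans were extracted with Agilent Feature Extraction 8.5.1.1. The deposited table holds 1 column per cross and age, each standing for 3 animals before birth and 4 after it, in what was read as log2 units as the authors deposited them. How the animals of a column were combined, how the arrays were normalised and the base of the logarithm are not given in the sources used here. The values run from −0.64 to 21.75 with 0 missing cells. Natural or decimal logarithms of such size would exceed any scanner, and the highest values also exceed log2 of a 16-bit signal. Differences are therefore given in log2 units on the deposited scale and not as folds. Column medians for the Piedmontese cross at 60, 135, 195 and 280 days and 3, 7, 12, 20, 25 and 30 months were 7.36, 7.21, 6.88, 5.88, 6.31, 6.37, 6.18, 5.90, 6.10 and 6.32. For the Wagyu cross they were 7.28, 6.95, 6.79, 6.30, 6.14, 6.11, 6.31, 6.07, 6.33 and 6.38, so the columns had not been brought to a common median.

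A deposited list of dyes and scans gave the layout: 36 arrays on 9 slides, each array holding a Piedmontese and a Wagyu sample of the same age in opposite dyes. Each postnatal column had 2 samples in each dye. Before birth the dyes were unbalanced. Piedmontese columns had 2 samples in Cy3 and 1 in Cy5 at 60 and 280 days, and the reverse at 135 and 195 days. The difference between the crosses at a single fetal age can therefore carry a dye effect that is balanced out after birth. A dye effect of the same size at each age would cancel in the mean of the 4 fetal ages. Fetal samples were on 3 slides, those of 3 to 20 months on 4 and those of 25 and 30 months on 2, with no slide shared. Differences between the crosses and steps inside a slide set therefore fall within slides, while comparisons across birth or from 20 to 25 months also compare slides. A slide term could not be fitted since each column averages over slides. The labels do not say whether an animal was sampled at several ages, so p-values treat the columns as independent, and 72 counts animal-by-age samples. The sex of the animals is not given either.

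Of 21475 rows, 12276 carried 1 gene symbol in the platform annotation and 9199 none. The symbols of 12153 rows were found in a current bovine gene table and 0 were changed. There were 11329 genes, 867 of them with more than 1 row, and a gene was described through its row with the highest mean. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a constant prior) on the deposited values, with age as a factor of 10 levels and cross, which leaves 9 residual degrees of freedom. Contrasts were 280 minus 60 days, 3 months minus 280 days, 30 minus 3 months, the mean of the 6 postnatal minus the 4 fetal ages, the steps between neighbouring ages, and Piedmontese minus Wagyu. Whether the cross difference itself differed by stage was tested on its 10 values per age (8 degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all rows, with a threshold of 0.05. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.

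The comparisons, tests, 24 gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except for those named below as later. The rule named the 8 genes with the largest passing difference in each direction that had the same sign in both crosses, or at 8 of 10 ages for the cross comparison. It also named the 10 genes with the largest F for age, the 5 smallest p in each direction for cross by stage and 2 in each direction for a step. Up to 2 members at each end of a list, and MSTN, were named as well. XIST, and rows named among the postnatal ages alone, were chosen after their values were seen. Lists were tested on 1 row per gene with camera at its preset correlation of 0.01, which passed 15, 8, 11 and 17 of 24 lists for the prenatal, birth, postnatal and postnatal minus prenatal changes and 10 for cross. With an estimated correlation 0 lists passed, and the smallest adjusted p-values were 0.31, 0.11, 0.25, 0.25 and 0.13. For the crosses the list means were tested by an exact two-sided sign-flip permutation over 10 ages (1024 flips).

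On simulated data of the same shape, with 200 of 21475 rows changed by 1 log2 unit, 96.5% were recovered for cross, 22% for the birth change, 33.5% for cross by stage and 94% for postnatal minus prenatal. With a change of 2 these were 99.5%, 93.5%, 96% and 100%, and with 0.5 they were 42%, 0%, 0% and 36%. Alternatives were quantile normalisation, the 25% of rows with the lowest mean left out, a trended robust prior, rows of a gene averaged, each age left out in turn, no age block for cross, stage in place of age, and a trend over the rank of age. Centring each column on its median, the mean of the 3 XIST rows as a covariate, the 6 postnatal ages alone, and leaving out 60, 135 and 195 days were added after the data were seen. Scans of single arrays were not used.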

Results

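Gene expression was measured by array in longissimus dorsi muscle (LD, the long muscle of the back and loin) of cattle of 2 crosses, Piedmontese by Hereford and Wagyu by Hereford. The muscle was sampled at 10 ages: 60, 135, 195 and 280 days of gestation, and 3, 7, 12, 20, 25 and 30 months after birth. Piedmontese cattle are known for heavy muscling and carry an inactive form of myostatin (MSTN), a protein that limits muscle growth, and Wagyu cattle are known for fat within the muscle. The deposited table has 1 column per cross and age, 20 in all, and each column stands for 3 animals before birth or 4 animals after it. There was therefore no replicate within a cross and age, and the 2 crosses served as the 2 samples of an age. The 72 animal-by-age RNA samples were run on 36 arrays, whose number limits the precision. Column medians lay between 5.88 and 7.36 on the deposited log2 scale. The correlation between columns, across genes that are not independent replicates, ran from 0.838 to 0.997. Between the crosses at the same age it ran from 0.987 to 0.997. Differences below are in log2 units on that scale, and an error after ± is the standard error of the limma estimate. For changes with age it shares 1 residual over all ages. The cross differences behind that residual had an SD over rows of 0.40 to 0.62 at fetal and 0.28 to 0.37 at postnatal ages. Errors of fetal changes may therefore be too small and those of postnatal steps too large.

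Age separated the samples far more than cross did. Of 21475 array rows, 18777 differed between ages, and the 10 genes with the largest F statistic ranged over 7.24 to 13.99 log2 units across the ages. The muscle genes among them were CKMT2 (the mitochondrial creatine kinase of striated muscle), MYL4 (the embryonic and atrial myosin light chain) and ANKRD23. KIF15 (a kinesin of the mitotic spindle) and SPC24 (a kinetochore protein) serve cell division, and IGF2BP3 is a fetal RNA-binding protein. The others were KLHL33, ETNPPL, MAGED4B and CFAP90. The lowest range was that of MAGED4B and the highest that of CKMT2.

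The prenatal change, 280 days minus 60 days of gestation, compares the tissue sampled at the first and last fetal ages. It holds both the maturation of muscle and any change in other tissues within the sample, and these were not told apart. Of the 8 genes named for the largest rises, 4 act in energy metabolism. FBP2 (muscle fructose bisphosphatase) rose by 14.88 ± 0.77 and CKMT2 by 12.78 ± 0.28. PDK4 (a kinase that restrains glucose oxidation) rose by 12.61 ± 0.40 and UCP3 (a mitochondrial carrier of muscle) by 12.30 ± 0.47. The largest adjusted p of these 4 genes was 2.93e-11. RPL3L (the striated muscle form of a ribosomal protein), LRRC39, ART3 and KLHL33 rose by 10.57 to 12.26. Among the genes that fell, MYL4 fell by 12.58 ± 0.32 and CRABP1 (a retinoic acid binding protein) by 12.51 ± 0.34. COL2A1 (cartilage collagen) fell by 11.76 ± 0.42, KRT15 (a keratin of surface epithelium) by 11.54 ± 0.52 and POSTN (periostin, a matrix protein) by 11.17 ± 0.42. LAMP5, COL11A1 (a cartilage collagen) and SPP1 (osteopontin) fell by 11.07, 11.01 and 10.37. In all, 13100 rows passed, 3988 higher and 9112 lower at 280 days.

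By gene list, 11 of 13 measured fast fibre genes rose (camera adjusted p = 1.35e-07, and adjusted p = 0.31 with an estimated correlation). ACTN3 (fast fibre alpha-actinin) rose by 10.34 and MYH1 (a fast myosin heavy chain) by 9.09, while PVALB (the calcium buffer parvalbumin) fell by 2.42. All 15 genes of the glycolysis and glycogen list rose, PYGM (muscle glycogen phosphorylase) by 8.56 (adjusted p = 1.69e-12, and 0.31 with an estimated correlation). In the oxidative phosphorylation list 28 of 29 genes rose, COX7A1 (a muscle subunit of cytochrome oxidase) by 4.98 (adjusted p = 6.98e-14, and 0.31 with an estimated correlation). The citrate cycle and fatty acid oxidation list had 15 of 18 genes higher and 1 lower (adjusted p = 2.27e-08, and 0.31 with an estimated correlation). The slow fibre list had 7 of 9 higher, CSRP3 (a muscle LIM protein) by 4.68 (adjusted p = 4.33e-05, and 0.31 with an estimated correlation). Immediate early genes were higher in 12 of 15 and lower in 2, with ATF3 at 7.88 (adjusted p = 6.8e-05, and 0.32 with an estimated correlation), though the list missed the threshold with centred columns (adjusted p = 0.073). Circadian genes were higher in 7 of 10 and lower in 1, and antigen presentation genes higher in 7 of 16 and lower in 2 (adjusted p = 0.0041 and 0.0045, and 0.31 and 0.32 with an estimated correlation). Heat shock genes were higher in 6 of 12 and lower in 2 (adjusted p = 0.0045, and 0.42 with an estimated correlation), and missed the threshold after quantile normalisation (adjusted p = 0.22).

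Proliferation and matrix genes moved the other way. Of 23 cell cycle genes 22 fell and MCM3 rose by 5.41 (adjusted p = 1e-09, and 0.31 with an estimated correlation). RRM2 (a subunit of ribonucleotide reductase) fell by 8.68 and CCNB2 (cyclin B2) by 8.24, and PCNA, at −0.79 as deposited, stood at 0.55 after quantile normalisation. In the extracellular matrix list 18 of 19 genes fell, TNC (tenascin C) by 8.40 (adjusted p = 1.66e-05, and 0.32 with an estimated correlation). In the cartilage and tendon list 10 of 11 fell and 1 rose (adjusted p = 0.0057, and 0.32 with an estimated correlation). Fetal contractile isoforms were lower in 8 of 10 genes and higher in 1, with MYH3 (embryonic myosin heavy chain) at −10.08 (adjusted p = 0.0057, and 0.42 with an estimated correlation). Imprinted and fetal growth genes were lower in 7 of 12, with MEST at −6.61 (adjusted p = 0.029, and 0.42 with an estimated correlation). Of the 13 genes of myostatin and activin signalling 8 fell, INHBA (an activin subunit) by 7.58 and MSTN by 4.09 ± 0.35 (list adjusted p = 0.016, and 0.42 with an estimated correlation). The list of myogenic regulators had 4 higher and 7 lower of 12 (adjusted p = 0.97): MYF5 and MYOG, regulators of muscle precursors, fell by 4.54 and 4.08, and MYF6, the regulator of mature fibres, rose by 5.83. Adjusted over the list alone, the counts above were the same except for 16 genes higher in the citrate list, 6 in the antigen presentation list and 8 lower in the imprinted list. Relative to the median gene, the fast fibre list stood at 5.17 and the cell cycle list at −4.53. The median of all rows was −0.34 as deposited and 0.15 after quantile normalisation, where 7955 rows passed as higher and 6575 as lower (12850 and 4784 with centred columns). Among rows that passed both ways 268 changed sign, and the counts of the ribosomal, macrophage, lymphocyte and endothelial lists moved with the scaling. Higher and lower counts were 3 and 8 after quantile normalisation and 5 and 7 with centred columns in the myostatin list. They were 1 and 8, and 4 and 6, in the imprinted list, and 10 and 0, and 15 and 0, in the antigen presentation list.

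**Figure D1:**
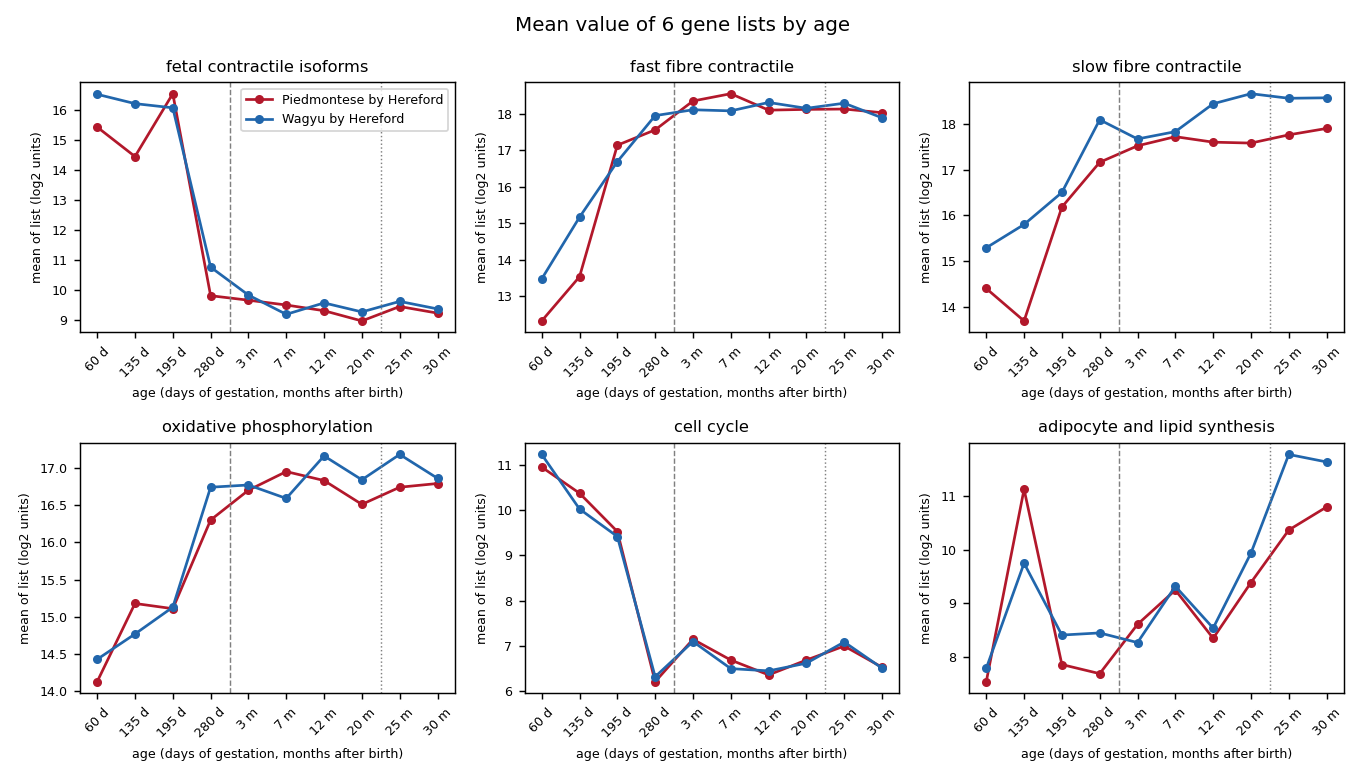
Mean value (log2 units) of 6 gene lists at each of the 10 ages in Piedmontese by Hereford (red) and Wagyu by Hereford (blue) samples, 1 point per deposited column. The dashed line marks birth and the dotted line the change of slides between 20 and 25 months; the fetal contractile mean was 16.30 at 195 days and 10.30 at 280 days, and the adipocyte mean 8.44 at 3 months and 11.22 at 30 months.

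Within gestation, the steps had different leading genes. From 60 to 135 days 4198 rows passed. The fat cell genes CIDEC (a lipid droplet protein) and ADIPOQ (adiponectin) rose by 9.16 ± 0.44 and 7.86 ± 0.64, and the epithelial keratins KRT5 and KRT15 fell by 8.39 ± 0.42 and 7.13 ± 0.52. From 135 to 195 days 3211 rows passed, with EEF1A2 (the elongation factor of muscle and nerve) at 8.31 and KLHL33 at 7.78, against LOC511158 at −6.32 and BOLA-N (a cattle class I histocompatibility gene) at −6.02. From 195 to 280 days 10265 rows passed, the most between any neighbouring ages. PDK4 rose by 10.99 ± 0.40 and UCP3 by 9.12 ± 0.47, and MYL4 and MYH8 (perinatal myosin heavy chain) fell by 11.98 ± 0.32 and 11.72 ± 0.56. As deposited, 1623 rows were higher and 2575 lower in the step from 60 days, 1175 and 2036 in the next, and 3051 and 7214 in the last. After quantile normalisation these were 2795 and 2514, 2279 and 2109, and 6761 and 5642, and with centred columns 3852 and 1987, 3257 and 1631 (4888 in all), and 10935 and 4406.

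Between 280 days of gestation and 3 months after birth, 13 of 16 genes of the antigen presentation and interferon list rose (camera adjusted p = 8.36e-12, and adjusted p = 0.11 with an estimated correlation). The members BOLA, IFIT2 and MX2 did not pass (0.60, −0.09 and −0.11). IDO1 (an interferon-induced enzyme of tryptophan breakdown) rose by 5.57 ± 0.32 and BOLA-N by 5.45 ± 0.57. CD74 (the class II invariant chain) rose by 5.34 ± 0.24, GBP1 (an interferon-induced GTPase) by 4.72 ± 0.55 and BOLA-DRA (a class II chain) by 4.64 ± 0.29. SCN4B (a sodium channel subunit), ABAT (GABA transaminase) and STBD1 (a glycogen-binding protein) rose by 5.09, 5.04 and 4.67. OXT (oxytocin) fell by 6.94 ± 0.44, TPD52L1 by 5.63 ± 0.27 and CATHL1 (an antimicrobial cathelicidin of neutrophils) by 5.60 ± 0.92. Decreases also passed for PNMT (the enzyme that makes adrenaline, −5.59 ± 0.39) and CA9 (a hypoxia-induced carbonic anhydrase, −5.05 ± 0.25). ZNF475, CDKN1A (a cell cycle inhibitor) and C15H11orf52 fell by 4.99, 4.30 and 4.19, and MSTN rose by 2.65 ± 0.35 (adjusted p = 4.36e-05). In all, 6148 rows passed, 2963 higher and 3185 lower, or 4009 and 4418 after quantile normalisation and 3112 and 6201 with centred columns.

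In other lists, macrophage and myeloid genes rose in 11 of 15, LYZ (lysozyme) by 2.57, and cell cycle genes in 12 of 23, RRM2 by 3.02 (both adjusted p = 3.11e-06, and 0.55 with an estimated correlation). Extracellular matrix genes were higher in 8 of 19 and lower in 2, with COL15A1 at 2.92 and THBS1 at −2.28 (adjusted p = 0.0058, and 0.91 with an estimated correlation). Ribosomal protein genes fell in 21 of 26, RPL22 by 2.38 and RPL3 by 2.05 (adjusted p = 2.45e-10, and 0.72 with an estimated correlation). Imprinted and fetal growth genes fell in 6 of 12, IGF2BP3 by 2.33 and IGF2 (a fetal growth factor) by 1.86, and NNAT rose by 1.05 (adjusted p = 0.013, and 0.79 with an estimated correlation). Myostatin and activin signalling rose in 5 of 13 while FST (follistatin, an inhibitor of myostatin) fell by 2.18, and glycolysis rose in 4 of 15 (adjusted p = 0.025 and 0.027, and 0.91 and 0.96 with an estimated correlation). Of 17 lymphocyte genes 7 rose, CD3E (a T cell receptor chain) by 2.41, 1 fell, and the list did not pass (adjusted p = 0.072). Adjusted over the list alone, 24 ribosomal and 7 imprinted genes fell. There 12 macrophage, 9 matrix and 9 lymphocyte genes rose, and 1, 3 and 1 fell. Fetal and postnatal samples were on different slides, so age and slides cannot be separated here. With each column centred on its median, 9313 rows passed in place of 6148.

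After birth, from 3 to 30 months, the leading change was a rise of fat cell genes. CIDEC rose by 6.04 ± 0.44, FABP4 (the fat cell fatty acid carrier) by 5.18 ± 0.72 and ADIPOQ by 4.27 ± 0.64. CCN5 (a matricellular protein) rose by 5.33 ± 0.43 and TRARG1 (a protein of glucose transporter vesicles) by 5.13 ± 0.42. ACSM1 (an acyl-CoA synthetase), THRSP (a regulator of fat synthesis) and MAL2 rose by 4.91, 4.89 and 3.93. The globin genes HBG, HBB and HBA, transcripts of red cell precursors, fell by 3.73, 3.69 and 3.34. The erythroid list had 4 genes lower and 2 higher, AHSP at 1.14 and HBE1 at 0.64, and did not pass (camera adjusted p = 0.079). INHA (an inhibin subunit) fell by 3.65 ± 0.32, NR4A3 (an immediate early receptor) by 3.49 and SOCS2 (an inhibitor of growth hormone signalling) by 3.41. NGEF and PTX3 were lower by −3.15 and −2.97. As deposited 4711 rows passed, 3962 higher and 749 lower, with a median of all rows of 0.31. After quantile normalisation 2505 were higher and 2672 lower, and with centred columns 3635 and 1549.

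In the adipocyte and lipid synthesis list 18 of 23 genes rose and none fell (camera adjusted p = 1.91e-11, and adjusted p = 0.52 with an estimated correlation). Adjusted over the list alone 20 rose, and the list mean stood 2.50 above the median gene. Cell cycle genes fell in 11 of 23, RRM2 by 2.04, while PRC1 rose by 0.96 (adjusted p = 1.33e-10, and 0.25 with an estimated correlation). In the antigen presentation list 5 of 16 genes fell and 1 rose (adjusted p = 5.41e-07, and 0.25 with an estimated correlation), and the interferon-induced genes MX1 and ISG15 fell by 2.84 and 2.33. Matrix genes fell in 4 of 19, COL1A1 by 2.01 and COL1A2 by 1.53, and 1 rose (adjusted p = 0.001, and 0.52 with an estimated correlation). Imprinted genes fell in 4 of 12, MEST by 2.94 and IGF2 by 2.39, and 1 rose (adjusted p = 0.001, and 0.52 with an estimated correlation). Immediate early genes were lower in 4 of 15 and higher in 1 (adjusted p = 5.15e-05, and 0.52 with an estimated correlation). Endothelial genes were lower in 3 of 16 and higher in 1, and lymphocyte genes lower in 1 of 17 (adjusted p = 0.002 and 0.0048, and 0.53 and 0.52 with an estimated correlation). Glycolysis genes were lower in 3 of 15 and higher in 1, fast fibre genes lower in 1 of 13, and fetal contractile genes lower in 2 of 10. Camera gave adjusted p = 0.00012, 0.0064 and 0.021 (0.52, 0.55 and 0.53 with an estimated correlation). These lists missed the threshold after quantile normalisation (0.093, 0.46 and 0.38). Adjusted over the list alone, these counts were the same except for 12 cell cycle, 4 glycolysis and 0 fast fibre genes lower, and 2 imprinted genes and 1 fetal contractile gene higher. MSTN was −0.82 ± 0.35, short of the threshold (adjusted p = 0.097). The first and last of these ages lay on different slides, and with the 25% of rows of lowest mean value left out 2827 rows passed.

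Steps between neighbouring postnatal ages were smaller. From 3 to 7 months 272 rows passed (quantile normalised 804), with PLEKHH3 at 2.14 and CCN5 at 2.10 against PDK4 at −3.66 and NR4A3 at −3.23. From 7 to 12 months 356 passed (quantile normalised 1033), with GPR85 at 3.79 and CHRNA10 at 2.62 against OTUD1 at −4.11 and COMP (a cartilage and tendon matrix protein) at −2.92. From 12 to 20 months 491 passed, 73 higher and 418 lower (quantile normalised 302 and 296), and CIDEC and HBB rose by 3.34 and 3.29 while GPR85 and ANKRD37 fell by 4.02 and 2.85. From 20 to 25 months 1926 passed, 1870 higher and 56 lower (quantile normalised 782 and 848), with THRSP at 2.88 and CATHL5 at 2.82 against CISH at −2.85 and PDK4 at −2.45. This step crossed a change of slides, and the 10% of rows with the lowest mean moved by a median of 0.77, against −0.11 to 0.092 in the other postnatal steps. With centred columns 949 rows passed, and with the 25% of lowest rows left out 345. From 25 to 30 months 603 passed, 470 higher and 133 lower (quantile normalised 815 and 797), with PDK4 at 6.29 ± 0.40 and ANGPTL4 (an inhibitor of lipoprotein lipase) at 3.88 ± 0.68 against HBG at −5.41 and HBB at −5.31. Centred on their medians, the columns gave 732, 923 and 910 rows for the steps that began at 3, 7 and 25 months.

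Comparing the mean of the 6 postnatal ages with the mean of the 4 fetal ages asks which genes differ in mean level between the stages. It does not show when a gene changed. Higher after birth were ETNPPL (8.52 ± 0.14), CKMT2 (8.49 ± 0.13), SCN4B (8.42 ± 0.16), UCP3 (8.11 ± 0.21) and FBP2 (8.03 ± 0.35). EEF1A2, KLHL33 and ANKRD23 were higher by 6.69, 6.62 and 6.60. Lower were the embryonic and perinatal myosins MYH3 (−9.46 ± 0.30) and MYH8 (−8.86 ± 0.25), MYL4 (−8.43 ± 0.15) and IGF2BP3 (−7.25 ± 0.13). CHRNG (the fetal subunit of the acetylcholine receptor) stood at −7.67, HBG at −7.44, BCAT1 (a branched-chain amino acid transaminase) at −7.32 and ARHGAP36 at −7.87. Several of these genes changed within gestation. MYL4 and MYH8 fell by 11.98 and 11.72 in its last step, and CKMT2, UCP3 and FBP2 rose by 12.78, 12.30 and 14.88 over the prenatal change. In the birth change MYH3, MYH8 and CHRNG did not pass (−1.23, −1.29 and 0.17), and MYL4 rose by 1.01. Others did change there, SCN4B by 5.09 and IGF2BP3 by −2.33. All 26 ribosomal protein genes were lower after birth, with RPL7 at −3.55 (camera adjusted p = 0.00013, and adjusted p = 0.55 with an estimated correlation), and quantile normalisation left 25 lower and 1 higher. In the oxidative phosphorylation list 28 of 29 genes were higher (adjusted p = 7.13e-15, and 0.25 with an estimated correlation). The exception, COX6B1, stood at −0.27 as deposited and was among the 29 higher after quantile normalisation. All 15 glycolysis genes, all 9 slow fibre genes and 12 of 13 fast fibre genes were higher (adjusted p = 7.07e-11, 1.37e-05 and 1.35e-07, each 0.25 with an estimated correlation). Antigen presentation genes were higher in 13 of 16, with BOLA-DQB at 4.52 (adjusted p = 2.97e-08, and 0.25 with an estimated correlation). Imprinted genes were lower in 11 of 12 (adjusted p = 0.00037, and 0.25 with an estimated correlation). Adjusted over the list alone, 13 fast fibre genes were higher and the other counts were the same. Lists of other cells differed too. Of 16 endothelial genes 14 were lower, with KDR at −2.73 (adjusted p = 0.021, and 0.59 with an estimated correlation), and 8 of 13 erythroid genes were lower (adjusted p = 0.043, and 0.41 with an estimated correlation). Adjusted over the list alone 14 and 7 were lower, and both lists missed the threshold after quantile normalisation (adjusted p = 0.062 and 0.07). The macrophage, lymphocyte and Schwann cell lists had members on both sides and did not pass (adjusted p = 0.13, 0.095 and 0.96), the macrophage list passing after quantile normalisation (adjusted p = 0.023). In all, 15786 rows passed, 4767 higher and 11019 lower, or 7901 and 7919 after quantile normalisation and 11695 and 5996 with centred columns. The median of all rows was −0.30 as deposited, and the stages lay on separate slides. MSTN stood at −0.06 ± 0.16 as deposited (adjusted p = 0.75) and at 0.62 after quantile normalisation (adjusted p = 0.0087), so its direction here depended on the scaling.

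The comparison of the crosses asks what distinguishes Piedmontese from Wagyu muscle at the same age. Slow fibre genes were lower in the Piedmontese cross: the list mean differed by −0.79 (SD over ages 0.58, 10 ages) and was lower at 10 of 10 ages, with quantile normalised and with centred columns too. CSRP3 (−1.13 ± 0.21), MYL3 (−1.02 ± 0.17) and MYL2 (−0.94 ± 0.19), the last 2 being light chains of slow myosin, passed over all rows as deposited. With quantile normalisation CSRP3 missed the threshold (adjusted p = 0.067), and with centred columns MYL2 narrowly did. All 9 measured genes passed when adjusted over the list alone. An exact two-sided sign-flip permutation test of the list mean gave p = 0.00195, the smallest that 10 ages allow, and an adjusted p of 0.047 over the 24 lists; camera with an estimated correlation gave an adjusted p = 0.13. Within each set of slides the mean was −1.06 (4 fetal ages), −0.54 (4 ages from 3 to 20 months) and −0.74 (25 and 30 months). In the same sets the fast fibre mean differed by −0.68, 0.12 and −0.006, and the fetal contractile mean by −0.83, −0.10 and −0.16. Both of these lists were higher in the Piedmontese cross at 1 of 4 fetal ages. Before birth the lower values were therefore not confined to slow fibre genes, and why was not tested. From 12 to 30 months after birth the difference was larger in the slow fibre list than in these lists. At 3 and 7 months it was not: slow fibre −0.15 and −0.11, fast fibre 0.24 and 0.47, fetal contractile −0.17 and 0.31. The permutation tests here and below treat the ages as independent, and the labels do not say whether animals were sampled at several postnatal ages. For the other 23 lists the exact sign-flip permutation test gave adjusted p-values of 0.48 to 0.96.

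**Figure D2:**
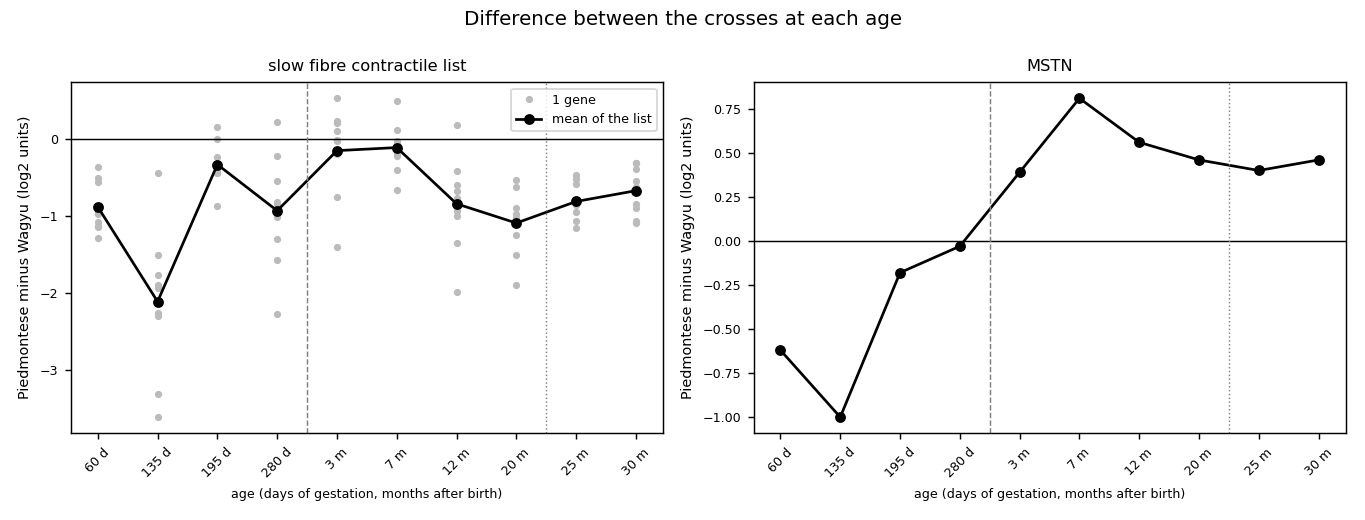
Difference between the crosses (Piedmontese minus Wagyu, log2 units) at each age for the 9 slow fibre genes (grey points) with their mean (black line), and for MSTN. The slow fibre mean lay below 0 at 10 of 10 ages, and MSTN lay below 0 at 4 of 4 fetal ages (3 of 4 with quantile normalised or centred columns, 280 days being above 0) and above 0 at 6 of 6 postnatal ages. The dashed line marks birth and the dotted line the change of slides between 20 and 25 months.

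Among single genes 60 rows passed between the crosses, 14 higher and 46 lower in the Piedmontese cross, or 47 and 73 after quantile normalisation and 33 and 84 with centred columns. The lowest were LOC515676 (−2.30 ± 0.20), BOLA-N (−1.76 ± 0.25), AKR1C4 (an aldo-keto reductase, −1.38 ± 0.22) and BOLA-DQA1 (a class II chain, −1.25 ± 0.24). Whether the array rows of the BOLA genes read both crosses alike was not tested. MCM3 (a DNA replication protein) was lower by −0.84 and MYL4 by −0.78, the other array row of MCM3 having the opposite sign. Higher in the Piedmontese cross were LOC507615 (1.75 ± 0.33), SPAG6 (1.03 ± 0.20), ATP6V1E2 (a proton pump subunit, 0.99 ± 0.17), ASPDH (0.98 ± 0.12), CSAD (a taurine synthesis enzyme, 0.95, with its other row opposite), GSTM3 (a glutathione transferase, 0.86), RIMS2 (0.67) and HACL1 (0.54). Apart from MYL4, named through its list, each gene named here had its sign at 8 or more of the 10 ages. At 60, 135 and 195 days the crosses also differed in XIST, the RNA of the inactive X chromosome of females, by −10.09, 4.20 and 3.69, while the labels do not give the animals' sex. In the 6 postnatal ages alone 400 rows passed, 155 higher and 245 lower, among them 55 of the 60. Of the ages left out in turn, 135 days gave 120 rows, and 3, 7, 12, 20, 25 and 30 months gave 20, 38, 17, 13, 12 and 19. Quantile normalisation gave 120 rows and centring 117. Of the genes named here, MCM3 missed the threshold after quantile normalisation (adjusted p = 0.063), and LOC507615, SPAG6 and BOLA-DQA1 with centred columns (0.052, 0.062 and 0.073).

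**Figure D3:**
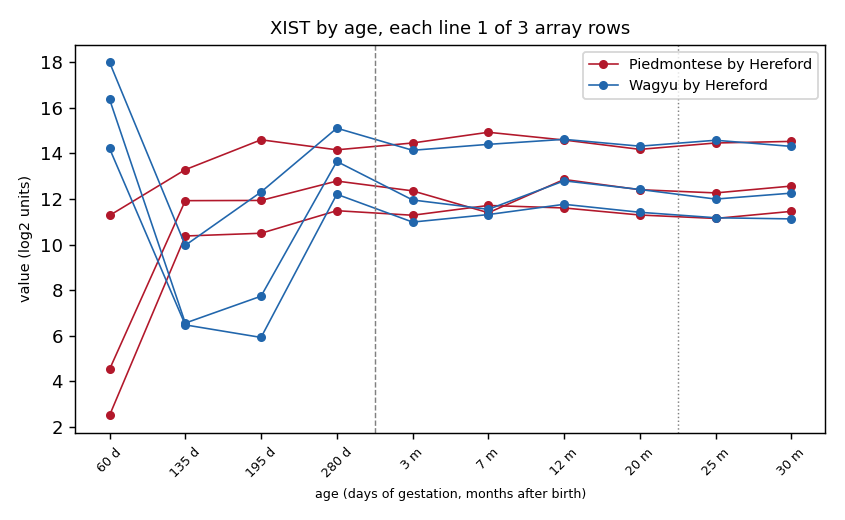
Value (log2 units) of the 3 array rows of XIST in the Piedmontese by Hereford (red) and Wagyu by Hereford (blue) samples at each age. The mean difference between the crosses was −10.09 at 60 days, 4.20 at 135 days and 3.69 at 195 days, and between −0.84 and 0.34 from 280 days on.

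MSTN, the gene whose inactive form Piedmontese cattle carry, did not differ between the crosses over all ages (0.12 ± 0.15, adjusted p = 0.94). Its Piedmontese minus Wagyu difference was −0.46 before birth (SD 0.44, 4 ages, negative at 4 of 4) and 0.51 after birth (SD 0.16, 6 ages, positive at 6 of 6). The value at 280 days, −0.03 as deposited, was 0.35 after quantile normalisation and 0.39 with centred columns, while the signs at the other 9 ages stayed. The exact permutation test over the 210 ways to divide the ages gave p = 0.0048, the smallest possible, for the difference of 0.97 ± 0.22 (0.0095 with either scaling). It takes the ages as alike in spread, which the SDs of 0.44 and 0.16 go against. Over all rows limma gave an adjusted p of 0.22. Opposite signs at every age before and after birth were found in 17 of 11329 genes (0.15%), against 0.195% by chance. The test of whether the crosses differ otherwise after birth than before it gave 4 rows. IFI47 (an interferon-induced GTPase, 1.57 ± 0.20, adjusted p = 0.013) and BOLA-DQB (2.61 ± 0.37, adjusted p = 0.017) shifted towards the Piedmontese cross after birth. RPL22 (−1.46 ± 0.22, adjusted p = 0.027) and BOLA-N (−1.79 ± 0.28, adjusted p = 0.037) shifted towards the Wagyu cross. Only RPL22 also passed under both scalings. Its row had a mean of 7.48 over all samples, far below the ribosomal list mean of 16.33 to 18.02 over the ages. BOLA-N and IFI47 missed the threshold with quantile normalisation (adjusted p = 0.2 and 0.058) and with centred columns (0.22 and 0.072), and BOLA-DQB with centred columns (0.08). BOLA-DQB, with a mean of 4.91 over all samples, rose by 4.27 between 280 days and 3 months. It was therefore dim before birth, where a difference between the crosses could have gone unseen. Class II DQ genes went both ways in the postnatal ages alone, BOLA-DQA1 at −1.72 and BOLA-DQA5, BOLA-DQB and BOLA-DQA2 at 3.05, 2.53 and 1.49. Whether their array rows read both crosses alike was not tested, so these need not be differences of transcript level. Fetal and postnatal ages lay on different slides, each array holding both crosses, and at 3 of the 4 fetal ages the crosses also differed in XIST. Dyes were unbalanced within a cross at each fetal age, one way at 60 and 280 days and the other way at 135 and 195 days. A dye effect of the same size at each age would cancel in the mean of the 4 fetal ages, but not at a single age. MSTN was negative at 60, 135 and 195 days, under both dye splits, with either scaling too, so its fetal sign did not follow the dyes. Next by p, and not passing, were BOLA-DQA5, JCHAIN and LOC507615 (3.90, 1.38 and 2.25) and GSTA1, KLF4 and JUNB (−2.58, −1.51 and −1.37). Without 60, 135, 195 or 280 days the count was 23, 11, 61 and 8, without 7 months 1, and without 12, 20 or 30 months 2. It was 0 without 25 months (limma, 997 rows at an unadjusted p under 0.05) and 0 with a trended robust prior (1060 such rows).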

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

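The tests of why differences recurred across the postnatal ages were chosen after the result was seen, and the splits of the samples before it. With 1 sample per cross and age, no sample could be set against others of its own group. The difference between the crosses itself differed before and after birth, by limma's test, in BOLA-DQB (2.61), BOLA-N (−1.79), RPL22 (−1.46) and IFI47 (1.57) as deposited. Only RPL22 also passed with quantile normalised and with centred columns: BOLA-N and IFI47 missed the threshold in both (adjusted p = 0.2 and 0.058 after quantile normalisation), and BOLA-DQB with centred columns (0.08). The RPL22 row was dim beside the ribosomal list, with a mean of 7.48. Of 100 splits of the 10 ages into 4 and 6, 1 split, the real one, gave 4 passing rows and the highest other gave 1. This excludes chance only if the ages are independent, which they are not where animals recur, and alike in spread. The SD over rows of the cross difference was 0.40 to 0.62 at the fetal ages and 0.28 to 0.37 at the postnatal ages. The splits therefore do not exclude chance here. MSTN changed by 0.97 between the stages, negative at 4 of 4 fetal ages (3 of 4 with either scaling, 280 days turning) and positive at 6 of 6 postnatal ages, with an exact permutation p of 0.0048 and a limma adjusted p of 0.22. After birth BOLA-N was lower in the Piedmontese cross at 6 of 6 ages and BOLA-DQB higher at 6 of 6. BOLA-DQB was dim before birth, so a fetal difference could have gone unseen. Dyes were balanced within a cross at each postnatal age. Before birth they were unbalanced one way at 60 and 280 days and the other way at 135 and 195 days. A dye effect of the same size would cancel in the fetal mean, but bears on the difference at a single fetal age.

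A wider pattern lay behind these genes: differences between the crosses recurred from one postnatal age to the next. The mean correlation across rows between the differences of 15 pairs of postnatal ages was 0.265, against 0.0499 for 24 pairs of 1 fetal and 1 postnatal age, and rows are not independent replicates. Different ages never shared an array. Sharing a slide set did not go with a higher correlation: pairs on different sets correlated 1.33 times as strongly as pairs on the same set (0.299 and 0.226). A slide effect common to both crosses cancels in their difference, so this comparison could hardly show one and decides nothing about slides. The same animals sampled at several postnatal ages may account for it, since the postnatal correlation exceeded that between fetal ages, where a fetus is sampled once, by 0.265; the labels do not say whether animals recur, and a breed difference that appears after birth would give the same value. A difference of the crosses at every age also stays open, with a covariance between fetal and postnatal ages of 0.275 of that between postnatal ages. The mean covariance between fetal ages, 0.00182 against 0.0266 after birth, goes against it, but single fetal pairs ran from −0.0397 to 0.0489. The share by correlation, the measure first used, was lower and would have argued against it, and covariance was preferred once fetal differences were seen to be more widely spread.

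Among 100 splits that exchange the crosses within ages, 1 split, the real one, gave 60 passing rows; the highest other gave 36. If the ages are independent, chance is excluded; if the same animals were sampled at several postnatal ages, chance differences between them would recur, and the splits do not exclude those. That other split exchanged the crosses at all ages except 60 and 135 days.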

How the results depend on the processing

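No named gene or list that passed its threshold turned to the other direction in the tabulated alternatives; some list members that passed both ways did after quantile normalisation. These were PCNA and NKG7 for the prenatal change and COX6B1, RPS27, SMAD2 and CD68 for postnatal minus prenatal. MSTN turned there too, not having passed as deposited. Centred columns also turned passing members, among them some of the erythroid, macrophage and antigen presentation lists in the prenatal change. Their higher and lower counts went from 0 and 7 to 7 and 5, from 0 and 10 to 6 and 4, and from 7 and 2 to 15 and 0. Of the 4 cross by stage genes, only RPL22 passed under both scalings. Named genes kept both their direction and their side of the threshold in 137 of 144 cases with quantile normalisation, 125 of 144 with a trended robust prior and 133 of 137 without the lowest rows. They kept both in 135 of 144 with rows of a gene averaged and in 134 of 144 with either centred columns or the XIST covariate. List calls kept their side in 104 of 120 cases with quantile normalisation, 113 of 120 with centring and 120 of 120 with rows averaged. Array signal over background was not available, so the floor of the dimmest rows is unknown.

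Averaging the rows of a gene tests fewer features and gave 10069 for age, 7204 for the prenatal, 3496 for the birth and 2361 for the postnatal change, 8534 for postnatal minus prenatal, 2388, 1861 and 5797 for the fetal steps, 157, 171, 253, 914 and 322 for the postnatal steps, 20 for cross and 7 for cross by stage. For the other alternatives the cause was not tested. Centring, added later, gave 9313 for the birth change, 4888 from 135 to 195 days, 732, 923, 949 and 910 for the steps that began at 3, 7, 20 and 25 months, and 117 for cross. Quantile normalisation gave 804, 1033 and 1612 for the steps that began at 3, 7 and 25 months and 120 for cross. Without the lowest 25% of rows the postnatal change had 2827, the step from 20 months 345 and cross by stage 11. Cross by stage had 0 with a trended robust prior (limma, 1060 at an unadjusted p under 0.05), 21 with the XIST covariate, which kept all 4, and 1379 without 60, 135 and 195 days, where 280 days alone stands for gestation; the last 2 were added later. Cross had 0 rows without the age block (limma, 77 at an unadjusted p under 0.05), where the spread between ages enters the error, and 400 in the 6 postnatal ages alone, added later.

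Leaving out 1 age at a time gave 12 (without 25 months) to 120 rows (without 135 days) for cross, and 0 (without 25 months) to 61 (without 195 days) for cross by stage. Gene lists by cross went from 1 to 0 (0 to 0 over the ages left out), since 9 ages, or the 6 postnatal ages (0 lists), cannot reach the threshold after adjustment; the slow fibre mean stayed between −0.87 and −0.64.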

Other observations

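The tests of dyes, column offsets, slides and immediate early genes in this part were chosen after the result was seen; those of genes that escape X inactivation, of glucocorticoid-induced genes and of splits of the ages were written before theirs. The mean of the adipocyte and lipid synthesis list was 7.67 at 60 days, 10.44 at 135 days and 8.13 at 195 days, with no test of the list at these steps, and CIDEC stood at 2.71, 11.87 and 6.48. The list mean was 1.38 higher in the Piedmontese sample at 135 days, and −1.41 and −0.84 relative to Wagyu at 25 and 30 months, with no test at a single age. At 60 days the muscle samples held high levels of KRT5 (14.33), KRT15 (14.41) and COL2A1 (16.25), which at 280 days stood at 4.75, 2.88 and 4.49. KRT5 and KRT15 mark surface epithelium and COL2A1 cartilage, so the tissue within the samples may have changed along with the muscle in the prenatal change.

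PDK4, a gene raised by fasting, swung after birth from 16.31 at 3 months to 9.93 at 25 months and back to 16.22 at 30 months. Erythroid list means were 5.15 at 12 months, 6.94 at 25 months and 5.62 at 30 months. The immediate early list, which tissue handling can raise, was higher in the Piedmontese cross at 3 of 4 fetal ages (mean 0.40) and at 0 of 6 postnatal ages (mean −0.64), with each scaling too. The exact permutation p was 0.0048, the smallest possible, and 0.11 after adjustment over 24 lists. This permutation takes the ages as alike in spread, while the SD was 0.53 before birth and 0.20 after it. The Y-linked list had 3 measured genes, a list mean of 4.41 to 4.98 over the ages, and a cross difference of −0.06 (exact sign-flip permutation adjusted p = 0.65).

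XIST was lower in the Piedmontese sample at 60 days (−10.09) and higher at 135 and 195 days (4.20 and 3.69). Unbalanced dyes are argued against, since at 280 days, with dyes divided as at 60 days, the difference was 0.0837 of that at 60 days, and so is an offset of whole columns, whose largest median was 0.0679 of the smallest XIST difference. An unequal sex of the sampled fetuses may be the source: 11 genes that escape X inactivation, listed beforehand, shifted with XIST by a mean of 0.66, with 10 of 11 positive, at percentile 99.01 of 10000 random lists of like level. TXLNG (1.43), KDM6A (1.21) and ZFX (1.20) shifted most. The shift also sets opposite dye splits against each other. At 280 days, with dyes as at 60 days and XIST at −0.84, the members other than KDM6A (0.53) were again below 0. The median of all rows there was −0.31. The shift of these genes therefore cannot tell sex from dyes. The Y-linked list differed by −0.49, 0.12 and −0.14 at 60, 135 and 195 days. Unequal sex would have it run opposite to XIST, which it did only at 195 days. Of its 3 measured genes, SRY and TSPY had low means over all samples (3.995 and 3.43) and may not report sex. ZFY had a mean of 6.55, and the list mean was 4.41 to 4.98 over the ages. The median of all genes shifted by 0.33 the same way, and a biological difference between the crosses at these ages was not tested.

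Of the 8 named genes that fell between 280 days and 3 months, 6 had risen from 195 to 280 days, while OXT stood at 0.01 (adjusted p = 0.99) and CATHL1 fell by 3.91. The change of slides cannot be told apart from age, since the whole fall lies across it. Inside the fetal slides the 8 genes changed by a median of 4.07 from 195 to 280 days (−1.95 for OXT and CATHL1 alone), against −5.32 across birth, but they were chosen by their values at 280 days, so this excludes nothing. A glucocorticoid response near birth is a candidate explanation: the mean of 9 glucocorticoid-induced genes stood above that of 195 days and 3 months, 8 of 9 members with it (FKBP5 by 4.64, SGK1 at −0.61), at percentile 100 of random lists, which met the bound set beforehand. In a comparison added after that, they barely differed between 280 days and 3 months (0.30, percentile 92.4, 6 of 9 higher), so this stays open, and so does stress at sampling, where 15 immediate early genes also reached percentile 100 but differed by 0.27 from 3 months (8 of 15 higher). Maturation with age before birth was not tested apart from these.

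For postnatal against fetal ages, 1 of 100 splits of the ages, the real one, gave 15786 passing rows, and the highest other gave 15485. The 100 splits were drawn from 210, and ages form an ordered series, so this rank neither excludes chance nor sets birth apart. Without 280 days 16509 rows passed. The splits gave 1915 rows or more, which points to a structure of the samples by age, and the highest other moved 280 days to the postnatal side in place of 25 months.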
